A study of Arabidopsis thaliana with 36 samples.

How the data were processed

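Shoots and roots of Arabidopsis thaliana Col-0 were profiled on 36 Affymetrix ATH1 arrays, with 2 arrays for each of 18 groups defined by 2 tissues and 9 times. The plants were the controls of a stress series, handled like treated plants but given no stress. The deposited values are an intensity for each of 22810 probe sets, which the submitters' processing notes attribute to MAS5, and its version is not given in the sources used here. The authors scaled each array: the mean without the lowest and highest 2% of probe sets lay between 100.007 and 100.01 on every array. No further scaling was therefore applied. No value was missing or at or below 0.

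Signals were converted to log2 after adding 10, which is 10% of the trimmed mean. The 64 array control probe sets were set aside and read only as measures of RNA quality. Probe sets with a signal of at least 40 on at least 2 arrays were kept, which left 15089. The probe table paired 13513 probe sets with 1 gene and 503 with several, and left 8794 without a gene. Of the probe sets with 1 gene, 13436 were matched through the Entrez gene number to the reference gene table of assembly TAIR10.1, which was used for names only. Gene names were given only to probe sets with 1 gene, and 8115 of these were kept by the filter.

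Group means were fitted with limma 3.58.1 in R 4.3.3, with all arrays in 1 fit of 18 means, 18 residual degrees of freedom and 4.06 prior degrees of freedom. The contrasts were shoots against roots over all times and each time against 0 h within a tissue. Moderated F-tests covered any change over time in each tissue and the difference of the time courses between the tissues. An adjusted p under 0.05 (Benjamini-Hochberg, 2-sided) was the threshold throughout. Changes are given as log2 differences with their standard error (SE) and signals as mean ± SD.

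The genes named were chosen by a rule, only among the 8115 kept probe sets with 1 gene, so each rank holds among these. In shoots against roots, they were the 8 largest changes each way without overlap between the 18 and 18 arrays. For each time course and for the interaction they were the 8 with the smallest p, for the time courses among those whose group means spanned at least 1 on the log2 scale. Against 0 h they were the 4 largest each way at 1, 12 and 24 h and the 2 largest each way at the other times, with both arrays beyond both 0 h arrays. Up to 4 members of each list fixed in advance were named as well. Genes named from the added lists were chosen after their values were seen.

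Lists of genes with a shared role were tested with camera, against all other named probe sets, with a preset correlation between genes of 0.01 and again with an estimated correlation. Of the 20 lists, holding 350 genes, that were fixed before the data were examined, the probe table named 47 genes on the array, and 8 lists had the 3 kept members that a test needs. A further 25 lists were written after the names in the probe table were seen and before any test, and 24 of these were tested. Some lists share genes and so do not give separate evidence. All 4 kept touch and rapid stress genes are also in the wider rapid stress list. Of these, WRKY53 is also in the WRKY list and CML38 in the wider hypoxia and calmodulin-like lists. With 32 lists and 17 contrasts there were 544 tests, of which 128 passed with the preset correlation and 3 with the estimated one. The difference of each change between the tissues was tested in the same way (256 tests), an addition made after the data were seen, and 58 passed with the preset and none with the estimated correlation.

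The contrasts, tests, threshold, filter, fixed lists, rule for named genes and most alternatives were chosen before the data were examined. These alternatives were no pseudocount, a pseudocount of 50% of the trimmed mean, no filter and a stricter filter. They were also quantile normalization over all arrays or within each tissue, centring each array on its median, a trend and robust prior, a fit of 1 tissue alone, replicate number as a fixed or random block, and leaving out each array in turn. The 25S ribosomal RNA (rRNA) control signal of each array as a covariate was added after the data were seen. So was the share of root RNA on shoot arrays, the median over 89 probe sets of the shoot signal as a percentage of the mean root signal. These had a mean root signal of at least 512 and were at least 16-fold lower in shoots. The share that a fall would need is the loss of signal in shoots divided by the root signal at 0 h, and for a rise the gain divided by the root signal at that time. When 1 array was left out, the lone array of that group was assumed to vary like the other groups.

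Whether the replicate numbers paired shoots with roots was checked. After the group means were removed, the correlation of a shoot and a root array of the same time and number lay between -0.115 and 0.05, so no pairing was used. The procedure was tested on simulated data built from 15089 genes, with 200 changed genes in each of 5 simulations. For shoots at 12 h it recovered 31.9% of changes of 0.5, 86% of changes of 1 and 98.8% of changes of 2 on the log2 scale, with 3.9% false calls. For roots at 1 h the shares were 31.9%, 85.7% and 99.1%, with 5.2% false calls. These shares hold for the simulated noise only. Whether they hold where many genes shift together between arrays, as with RNA quality, was not tested. On the measured arrays the 1194 probe sets of roots at 1 h became 67 with the rRNA control signal as a covariate. The simulation therefore does not give the share of false calls in the measured data. No array and no column of values was left out.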

Results

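Transcript levels were measured in shoots and roots of plants that received the handling of a stress experiment without the stress. Sampling began on day 16, 3 h after lights on in a 16 h light period at 24 °C and 50% humidity, and followed at 0, 0.25, 0.5, 1, 3, 4, 6, 12 and 24 h. The 12 h samples were therefore taken 15 h after lights on, and the 24 h samples at the same hour of the day as the 0 h samples. Each tissue and time had 2 arrays. The labels do not say whether these came from separate plants, so the p-values measure the spread between samples, which may be technical, and the number of arrays limits their precision. Replicate arrays correlated at 0.971 to 0.992 across probe sets, which are not independent replicates, and the SD of their log2 difference was 0.182 to 0.386. The share of probe sets at or above the filter was 47.9 to 50.5% in shoots and 52.1 to 54.1% in roots. The median signal of the photosynthesis genes was 3872 to 5392 on shoot arrays and 28.8 to 67.6 on root arrays. That of the root marker genes was 42.3 to 89.9 on root arrays and 13.4 to 26.2 on shoot arrays.

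Shoots and roots were compared over all 9 times to show which transcripts each organ carries without stress. Among the 8 largest differences toward shoots of probe sets with 1 gene were 4 genes of carbon fixation and photosynthesis. SBPASE (AT3G55800) had a signal of 3030 ± 521 in shoots and 19.3 ± 3.29 in roots (SD, n = 18 each, log2 difference 6.68 ± 0.05 SE). PRK (AT1G32060) was higher by 7 ± 0.062, PSAE-1 (AT4G28750) by 6.7 ± 0.082 and LHCB4.2 (AT3G08940) by 6.6 ± 0.068. ECS1 (AT1G31580) differed by 7.85 ± 0.065, with signals of 5120 ± 642 and 12.4 ± 4.29, and AT1G23130, AT1G09310 and AT2G10940 by 7.51, 7.14 and 7.07. Their signals in roots were below the filter, so the pseudocount set their order: without it AT1G23130 (9.77) and AT2G10940 (9.54) lay above ECS1 (8.76). On the root side, the acyltransferase-family gene AT4G15390 differed by -6.95 ± 0.1 (4.15 ± 7.14 in shoots, 1640 ± 221 in roots). The peroxidase genes AT4G30170 and AT3G01190 differed by -6.39 ± 0.096 and -6.09 ± 0.08. The osmotin gene OSM34 (AT4G11650) differed by -6.19 ± 0.1 and AT3G13610, which encodes the enzyme of iron-mobilizing coumarin synthesis, by -6.11 ± 0.11. AT2G19970, AT4G39675 and AT5G01870 differed by -6.21, -5.94 and -5.89. Most of these had shoot signals near the background, such as 1.09 ± 0.811 for AT2G19970, so the pseudocount sets their size and order. Over all alternatives AT4G15390 ran from -9.49 to -4.96, AT2G19970 from -9.76 to -4.08 and AT4G39675 from -9.01 to -3.95. The adjusted p of these 16 genes was at most 3.2e-23.

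Over all probe sets, 13907 of 15089 (92.2%) differed, 4766 higher and 9141 lower in shoots, and 2536 and 3069 of them by at least 2-fold. The 18 shoot arrays had no overlap with the 18 root arrays for 7051 probe sets, where chance leaves 2.2e-08% of splits without overlap. The median of all genes was -0.33, which moved to -0.21 with quantile normalization (5436 higher, 8314 lower) and to -0.12 with each array centred on its median (5923 higher, 7692 lower). Beside that shift, the 7 photosynthesis genes were all higher in shoots (7 adjusted over the list alone), with a median of 5.63 and adjusted p = 1.1e-05 (adjusted p = 0.42 with an estimated correlation). Among the lists added once the probe names were known, 15 of 15 chloroplast metabolism genes were higher (median 5.34, adjusted p = 3.5e-10, adjusted p = 0.29 with an estimated correlation). So were all genes of the plastid genome, 33 for photosynthesis (median 3.18, 7.5e-15), 10 for the NDH complex (3.29, 4.3e-06) and 19 for gene expression (2.35, 4.1e-09), each with adjusted p = 0.42 with an estimated correlation. Lower in shoots were 35 of 41 class III peroxidases (median -2.66, adjusted p = 0.0034, adjusted p = 0.44 with an estimated correlation) and 21 of 23 hypoxia genes of the wider list (-2.26, 0.0071, adjusted p = 0.79 with an estimated correlation). Of the cytosolic ribosomal protein genes 95 of 97 were lower (-0.72, 3e-08, adjusted p = 0.59 with an estimated correlation). The sucrose transporter gene SWEET11 was higher in shoots by 5.09 ± 0.045, with SWEET1 at 2.16 and SWEET2 at 1.56. In all 6 of 7 SWEET genes were higher (median 0.78, adjusted p = 0.018, adjusted p = 0.42 with an estimated correlation).

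The other lists fixed in advance passed no test between the tissues. All 3 root markers were lower in shoots (3 adjusted over the list alone), PYK10 by -2.22 ± 0.091, EXPA7 by -1.34 and EXPA18 by -1.22 (median -1.34, adjusted p = 0.3). The touch and rapid stress genes CML38, STZ, CML23 and WRKY53 were lower by -2.26, -2.05, -1.21 and -0.52 (4 of 4, 4 adjusted over the list alone, median -1.63, adjusted p = 0.47). Of the heat shock genes 4 of 5 were lower (4 adjusted over the list alone, median -0.94, adjusted p = 0.75). Of the abscisic acid, drought and cold genes, COR15A and COR15B were higher in shoots by 2.4 and 2.02, while LTI30 and COR47 differed by -4.71 and -1.72. Their median was 0.15 and their mean -0.5. The test pointed up with adjusted p = 0.86 (4 members passed, 4 adjusted over the list alone). UGT78D1 and DFR were higher by 2.23 and 0.97 and UGT78D2 differed by -0.18 (flavonoid list, 3 passed, 3 adjusted over the list alone, median 0.97, adjusted p = 0.36). The glucosinolate genes AT2G31790, UGT74B1 and BCAT4 differed by 1.35, -0.35 and -0.27 (3 passed, 3 adjusted over the list alone, adjusted p = 0.83, with a median of -0.27 but a mean of 0.24 and a test pointing up). The auxin genes GH3.3, WES1 and IAA29 differed by -2.87, -1.95 and 0.87 (3 passed, 3 adjusted over the list alone, median -1.95, adjusted p = 0.82).

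The time course in shoots addressed which genes move over a day without stress. The starch genes DPE1 (AT5G64860) and PWD (AT5G26570) climbed to 536 ± 15.5 and 1030 ± 51 at 6 h (SD, n = 2). Their lowest signals were 39.5 ± 3.47 at 0 h and 103 ± 4.04 at 0.5 h, with ranges of 3.46 and 3.19 on the log2 scale. AT3G62550, of the universal stress protein family, ranged over 4.95, from 56.1 ± 10.7 at 1 h to 2010 ± 44.9 at 6 h. The chloroplast lipocalin gene CHL (AT3G47860) ranged over 3.37, from 71.4 ± 6.41 at 0.25 h to 830 ± 25 at 12 h. AT4G16146 had the largest F (314) among the named genes and fell to 16.4 ± 1.44 at 24 h from 394 ± 37.5 at 6 h. AT1G70820 and AT3G53990 were also highest at 6 h, with ranges of 3.21 and 2.88, while AT1G55960 was lowest at 6 h (113 ± 10.8) and highest at 24 h (2220 ± 252). The adjusted p of these 8 genes was at most 8.8e-16. In all, 9448 probe sets (62.6%) changed over time in shoots.

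**Figure D1:**
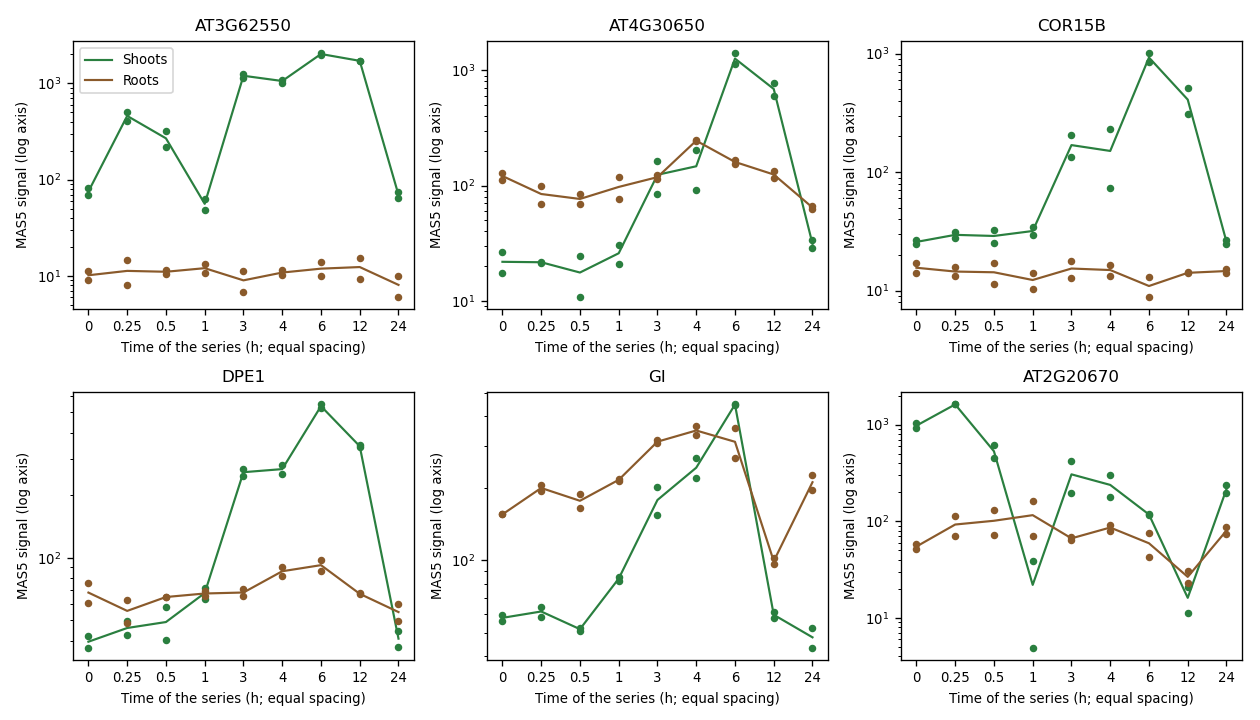
MAS5 signal (log scale) of 6 genes in shoots and roots at the 9 sampling times, spaced equally; points are single arrays and lines join the means of 2 arrays. In shoots AT3G62550 reached 2010 and DPE1 536 at 6 h.

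**Figure D2:**
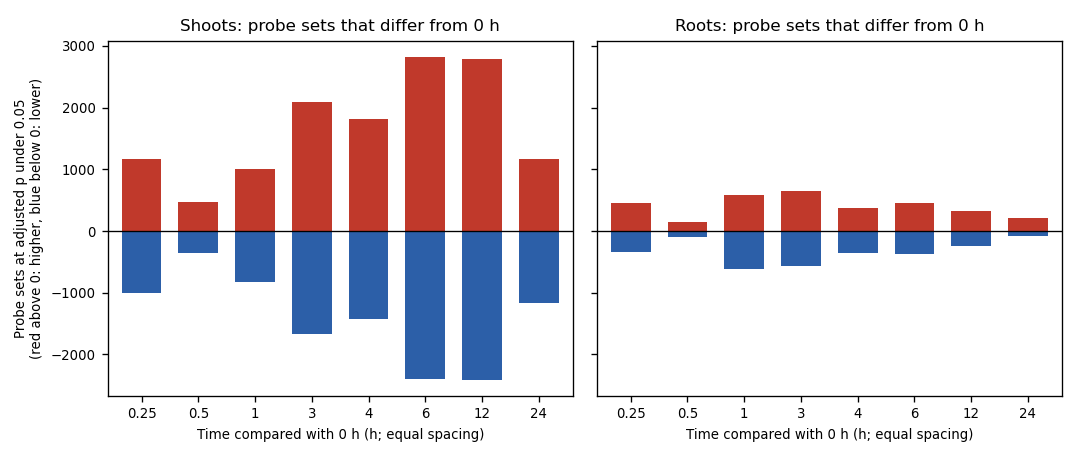
Number of probe sets higher (red) and lower (blue) than at 0 h, adjusted p under 0.05, at each time in shoots and roots, as bars. Shoots reached 5217 at 6 h and roots at most 1223 at 3 h.

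The samples of 0.25 and 0.5 h were the first after 0 h, and whether handling of the plants caused their changes was not tested. In shoots OSM34 fell by 3 ± 0.31 at 0.25 h and by 2.93 ± 0.31 at 0.5 h. Its signal went from 126 ± 50.3 to 6.54 ± 2.12 and 7.28 ± 0.439 (SD, n = 2; adjusted p = 2.5e-06 and 3.8e-06). These are signals near the background, and the change ran from -4.25 to -1.61 and from -4.05 to -1.59 over all alternatives. Since OSM34 is a gene with far higher signals in roots, root material on shoot arrays was examined after this fall was seen. The 89 probe sets abundant in roots and at least 16-fold lower in shoots had a median of 5.34 and 2.16% of their root signal on the 0 h shoot arrays. This share was 2.85 ± 0.605% at 4 h and 0.902 to 1.88% on the other shoot arrays, so some root material in the 0 h and 4 h shoot samples was not excluded. The fall of OSM34 at 0.25 h would need a share of 6.91% and that of PYK10 25.7%, against a measured difference of 2.22%, so such material was not excluded as a part of these falls. AT3G62550 rose by 2.45 ± 0.18 at 0.25 h (75.4 ± 9.2 to 458 ± 68.6, adjusted p = 3e-08) and AT3G19680 by 1.86 ± 0.21 at 0.5 h (adjusted p = 1.4e-05). AT5G62080 rose by 2.87 ± 0.7 at 0.25 h (adjusted p = 0.0088), and the chitinase-family gene AT2G43620 fell by 2.81 ± 0.83 (adjusted p = 0.026). At 0.5 h the expansin-like gene EXLA1 rose by 1.9 ± 0.49 and GAT1_2.1 fell by 2.43 ± 0.63 (adjusted p = 0.023 each). The counts were 1169 higher and 1006 lower at 0.25 h and 477 and 352 at 0.5 h.

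The heat shock genes AT5G51440 and AT5G48570 fell by 1.82 ± 0.43 and 1.63 ± 0.37 at 0.25 h (2 of 5 members, 2 adjusted over the list alone). The list had a median of -1.27 and adjusted p = 0.041 (adjusted p = 0.63 with an estimated correlation). PYK10 fell by 1.34 ± 0.27 at 0.5 h, the 1 of 3 root markers that passed (1 adjusted over the list alone, median -0.32, adjusted p = 0.041, adjusted p = 0.44 with an estimated correlation). Of the ribosomal protein genes, 33 of 97 fell at 0.25 h (median -0.26, adjusted p = 4e-18, adjusted p = 0.42 with an estimated correlation). At 0.5 h 1 fell (-0.16, 1.9e-09, adjusted p = 0.56 with an estimated correlation). Plastid genes rose at 0.25 h, 8 of 33 for photosynthesis (median 0.35, adjusted p = 0.00017) and 4 of 10 for the NDH complex (0.67, 0.00068). So did 2 of 12 mitochondrial probe sets (0.56, 0.003) and 3 of 11 sugar starvation genes (0.64, 0.027), while 1 sugar starvation gene fell. These 4 lists had adjusted p = 0.67, 0.51, 0.57 and 0.74 with an estimated correlation. At 0.5 h, 3 of 41 peroxidases and 1 of 32 UGT glycosyltransferases fell (adjusted p = 0.0011 and 0.011, adjusted p = 0.42 and 0.45 with an estimated correlation). The changes of the peroxidases would need a median share of root RNA of 3.35% at 0.5 h, 3.89% at 1 h, 4.52% at 3 h, 5.4% at 12 h and 4.23% at 24 h. The measured differences in share were 2.53, 2.47, 2.51, 2.58 and 2.53%, so root material was not excluded as a part of the peroxidase falls at any of these times. The 25S rRNA signal was 990.1 ± 60.7 at 0 h and 2170 ± 156 at 0.25 h. With it as a covariate the 2175 probe sets at 0.25 h became 129. Without shoot 0 h replicate 1 the counts at 0.25 and 0.5 h were 1046 and 241 (at 0.5 h 164 higher and 77 lower). Without 0 h replicate 2 the count at 0.5 h was 1329 and its balance turned, with 574 higher and 755 lower. Without 0.25 h replicate 1 or 2 the count at 0.25 h was 912 and 1201. At 0.5 h it was 541 and 255 without 0.5 h replicate 1 or 2, and 500 in shoots alone. AT2G43620, EXLA1, GAT1_2.1 and AT5G62080 each lost their call in a fit of shoots alone and without single arrays. These were 0 h replicate 1 and both 0.25 h arrays for AT2G43620, 0 h replicate 1 and both 0.5 h arrays for EXLA1, all 4 for GAT1_2.1, and replicate 2 of 0 and 0.25 h for AT5G62080. The covariate also ended the calls of AT2G43620, GAT1_2.1 and AT5G62080, no pseudocount that of AT2G43620 and the larger pseudocount that of GAT1_2.1. Their adjusted p reached 0.63, 0.43, 0.14 and 0.17 over all alternatives. Centred on the array median, 785 were higher and 1636 lower at 0.25 h.

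At 1 h in shoots the strongest changes were falls. AT2G20670 fell by 5.19 ± 0.43, from 978 ± 90.9 to 22 ± 24.1 (SD, n = 2; adjusted p = 4e-08), AT5G19120 by 3.65 ± 0.3 and AT3G15450 by 3.15 ± 0.29 (2000 ± 437 to 223 ± 92.2). AT5G19120 and AT3G15450, but not AT2G20670, belong to the wider sugar starvation list. Of this list 8 of 11 genes fell (median -1.56, adjusted p = 6.8e-12, adjusted p = 0.42 with an estimated correlation), among them AKINBETA1 by 0.97 ± 0.2. Rapid stress genes fell as well, AT4G27280 by 2.77 ± 0.36, STZ by 2.49 ± 0.53, AT1G32920 by 2.27 ± 0.37 and WRKY53 by 1.38 ± 0.41, as did 11 of 23 members of the wider list. Its median was -0.94 and adjusted p = 3.3e-12 (adjusted p = 0.42 with an estimated correlation). OSM34 fell by 3.15 ± 0.31. AT1G76240, AT3G44450, AT1G78170 and AT5G12940 rose by 1.78 ± 0.23, 1.67 ± 0.21, 1.61 ± 0.14 and 1.53 ± 0.33. In all 1010 probe sets were higher and 826 lower.

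Of the fixed lists at 1 h in shoots, 2 of 4 touch and rapid stress genes fell (3 adjusted over the list alone, median -1.08, adjusted p = 0.0071, adjusted p = 0.44 with an estimated correlation). All 4 are also in the wider rapid stress list, so this is no separate evidence. Of the heat shock genes AT5G48570 fell by 1.48 ± 0.37 (1 of 5, 2 adjusted over the list alone, median -0.84, adjusted p = 0.041, adjusted p = 0.63 with an estimated correlation). LTI30 fell by 0.74 ± 0.23 (1 of 4 abscisic acid, drought and cold genes, 1 adjusted over the list alone, adjusted p = 0.85). The median of that list was 0.24 and its mean 0.07, but the test pointed down. PYK10 fell by 0.97 ± 0.27 (1 of 3 root markers, 1 adjusted over the list alone, median -0.3, adjusted p = 0.28). Photosynthesis, flavonoid and glucosinolate genes had medians of 0.18, 0.09 and 0.09, with adjusted p = 0.71, 0.97 and 0.9 and 0 members past the limma threshold (0 at an unadjusted p under 0.05, 0 adjusted over the list alone). The glucosinolate test pointed down. The 3 auxin genes had a median of 0.58 (adjusted p = 0.94, 0 past the limma threshold, 3 at an unadjusted p under 0.05, 3 adjusted over the list alone, 2 of them up). Of the added lists, 5 of 41 peroxidases fell (median -0.26, adjusted p = 0.00026, adjusted p = 0.42 with an estimated correlation). So did 5 of 23 hypoxia genes (-0.19, 0.0099, adjusted p = 0.8 with an estimated correlation) and 3 of 5 WRKY genes (-0.93, 0.0013, adjusted p = 0.42 with an estimated correlation). The changes of the hypoxia genes would need a median share of root RNA of 6.93% at 1 h and 9.89% at 24 h, and that of AT4G39675 2.62% and 2.58%, so root material was not excluded as a part of these falls either. In contrast 4 of 15 cell division and histone genes rose (0.45, 0.0057, adjusted p = 0.67 with an estimated correlation). Without shoot 1 h replicate 2 the count of 1836 became 869 and 4 rapid stress genes passed. Without 0 h replicate 1 these were 6, and without 0 h replicate 2 the sugar starvation genes were 5. AT5G12940 lost its call without 0 h replicate 2 or 1 h replicate 2 (adjusted p = 0.094 and 0.12). With the 25S rRNA covariate 678 probe sets, 3 rapid stress and 4 sugar starvation genes passed and AT5G12940 did not (adjusted p = 0.25). The sugar starvation median moved from -1.56 to -1.59 while its median SE grew from 0.3 to 0.43, so these calls ended through the wider error. The rapid stress median shrank from -0.94 to -0.68 and its SE grew from 0.41 to 0.55. The split was 549 higher and 936 lower with arrays centred on their median, 641 and 809 with quantile normalization, and 695 and 905 without 0 h replicate 2.

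The 3 to 6 h samples lay later in the light period. In shoots the protochlorophyllide reductase gene PORB (AT4G27440) rose by 3.44 ± 0.26 at 3 h, from 179 ± 11.5 to 2040 ± 188 (SD, n = 2; adjusted p = 2.7e-09), and AT3G62550 by 3.82 ± 0.18. The pectin methylesterase inhibitor family gene AT5G62360 rose by 3.96 ± 0.28 at 4 h and 5.73 ± 0.28 at 6 h (7.54 ± 0.253 to 924 ± 7.75; 2.45 to 5.13 and 4.08 to 6.94 over all alternatives). AT1G56300 rose by 3.87 ± 0.25 at 4 h and AT4G30650 by 5.33 ± 0.3 at 6 h (21.8 ± 6.34 to 1260 ± 197). At 6 h COR15B rose by 4.71 ± 0.3, COR15A by 3.14 ± 0.4, DPE1 by 3.46 ± 0.13, PWD by 3.1 ± 0.13 and the clock gene GI by 2.76 ± 0.13. Falls included OSM34 by 3.2 ± 0.31 and STZ by 2.85 ± 0.53 at 3 h, AT4G27280 by 2.54 ± 0.36 and AT1G33055 by 2.52 ± 0.47 at 4 h. At 6 h AT1G65490 fell by 3.77 ± 0.15 and AT3G28270 by 3.7 ± 0.15. The counts were 2084 higher and 1663 lower at 3 h, 1817 and 1431 at 4 h, and 2816 and 2401 at 6 h.

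The abscisic acid, drought and cold genes rose at 4 h (3 of 4, 3 adjusted over the list alone, median 1.32, adjusted p = 0.018) and 6 h (4 of 4, 4 adjusted over the list alone, median 2.51, adjusted p = 0.0013). Both times had adjusted p = 0.42 with an estimated correlation. Touch and rapid stress genes fell at 3 h (3 of 4, 3 adjusted over the list alone, median -1.54, adjusted p = 0.013, adjusted p = 0.47 with an estimated correlation). At 4 h they fell too (3 of 4, 3 adjusted over the list alone, -1.14, 0.037, adjusted p = 0.58 with an estimated correlation). UGT78D2 and UGT78D1 of the flavonoid list fell by 1.03 and 0.73 at 4 h and by 1.53 and 0.85 at 6 h (2 of 3, 2 adjusted over the list alone). The list had medians of -0.73 and -0.85 and adjusted p = 0.042 and 0.045 (adjusted p = 0.42 and 0.43 with an estimated correlation). Of the wider diurnal list, 5, 4 and 7 of 12 genes rose and 1, 2 and 2 fell at 3, 4 and 6 h. The medians were 0.24, 0.19 and 2.97, with adjusted p = 0.033, 0.025 and 7.5e-05 (adjusted p = 0.46, 0.44 and 0.36 with an estimated correlation). At 6 h the largest were AT1G56300 (4.5 ± 0.25), AT1G07050 (4.32) and AT4G16146 (3.86). Rapid stress genes of the wider list fell, 14, 10 and 14 of 23 (medians -1.42, -0.94 and -1.19, adjusted p = 3e-09, 1.1e-06 and 1.2e-06, adjusted p = 0.44, 0.52 and 0.52 with an estimated correlation). So did 45, 44 and 66 of 97 ribosomal protein genes (adjusted p = 2.3e-16, 3.2e-19 and 3.1e-18, adjusted p = 0.42 with an estimated correlation at each time). Without shoot 0 h replicate 1 or 3 h replicate 1 the 3747 probe sets at 3 h became 2480 and 2206, and without 4 h replicate 2 the 3248 at 4 h became 2013. Centred on the array median 1344 were higher and 1765 lower at 4 h and 2152 and 2902 at 6 h. The 25S rRNA signal was 2536 ± 181 at 6 h, and with it as a covariate the counts at 3, 4 and 6 h were 1083, 842 and 1950. STZ at 3 h and AT4G27280 and AT1G33055 at 4 h then lost their calls (adjusted p = 0.26, 0.15 and 0.086).

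At 12 h in shoots, late in the light period, AT4G30650 and AT3G62550 were still higher than at 0 h by 4.46 ± 0.3 and 4.34 ± 0.18 (adjusted p = 7.7e-11 and 2.4e-14, n = 2). AT1G07050 was higher by 4.27 ± 0.2 and AT4G34950 by 3.99 ± 0.56. COR15B and COR15A were higher by 3.51 ± 0.3 and 2.48 ± 0.4, PWD by 2.91 ± 0.13 and DPE1 by 2.84 ± 0.13. AT2G20670 fell by 5.26 ± 0.43, from 978 ± 90.9 to 16.2 ± 6.93 (SD, n = 2; adjusted p = 2.2e-09). AT1G62510 fell by 4.47 ± 0.6, the calcium-binding protein gene AT4G27280 by 4 ± 0.36 and AT2G41250 by 3.47 ± 0.14. Of the wider rapid stress list 16 of 23 genes fell (median -1.43, adjusted p = 1.2e-08, adjusted p = 0.44 with an estimated correlation). Of the sugar starvation list 8 of 11 fell (-1.66, 2.6e-06, adjusted p = 0.44 with an estimated correlation). In all 2792 probe sets were higher and 2407 lower.

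The touch and rapid stress genes STZ, WRKY53 and CML23 fell at 12 h by 3.12, 1.98 and 0.99 (3 of 4, 3 adjusted over the list alone, median -1.54, adjusted p = 0.025, adjusted p = 0.52 with an estimated correlation). The other fixed lists passed no test at 12 h in shoots. COR15B, COR15A and COR47 rose (3 of 4, 3 adjusted over the list alone, median 1.78, adjusted p = 0.062). AT5G48570 and AT5G51440 fell by 1.92 and 1.43 (2 of 5 heat shock genes, 4 adjusted over the list alone, median -1.43, adjusted p = 0.091), as did WES1 and IAA29 by 1.47 ± 0.25 and 0.98 ± 0.27 (2 of 3 auxin genes, 3 adjusted over the list alone, median -0.98, adjusted p = 0.069). LHCB4.3 rose by 1.07 ± 0.19 and LHCB4.2 fell by 1.59 ± 0.2 (2 of 7 photosynthesis genes, 2 adjusted over the list alone, median -0.06, adjusted p = 0.81). PYK10 fell by 1.31 ± 0.27 (1 of 3 root markers, 1 adjusted over the list alone, median -0.3, adjusted p = 0.27). UGT78D1 rose by 0.8 ± 0.23 (1 of 3 flavonoid genes, 1 adjusted over the list alone, median 0.07, adjusted p = 0.85) and UGT74B1 by 0.36 ± 0.14 (1 of 3 glucosinolate genes, 1 adjusted over the list alone, median 0.23, adjusted p = 0.6). Ribosomal protein genes fell, 76 of 97 (median -0.45, adjusted p = 7.6e-22, adjusted p = 0.42 with an estimated correlation). So did 13 of 41 peroxidases (-0.39, 0.012, adjusted p = 0.5 with an estimated correlation) and 3 of 5 WRKY genes (adjusted p = 0.012, adjusted p = 0.42 with an estimated correlation). Of the wider diurnal list 7 of 12 rose and 2 fell (median 1.79, adjusted p = 0.0021, adjusted p = 0.42 with an estimated correlation), AT1G69570 by 2.29 ± 0.17.

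At 24 h in shoots, the hour of the day was that of 0 h, yet 1173 probe sets were higher and 1171 lower, 98 and 445 of them by at least 2-fold. AT1G19380 fell by 3.21 ± 0.36, from 374 ± 154 to 29.9 ± 3.59 (SD, n = 2; adjusted p = 6.5e-06). AT4G01870 fell by 3.07 ± 0.86 (adjusted p = 0.019), AT2G43620 by 2.85 ± 0.83 (adjusted p = 0.023), AT2G25735 by 2.81 ± 0.41 (adjusted p = 9.7e-05) and STZ by 2.75 ± 0.53. Of the wider rapid stress list 16 of 23 genes fell (median -1.31, adjusted p = 5.4e-12, adjusted p = 0.42 with an estimated correlation). Among them were AT1G32920 by 2.52 ± 0.37, AT4G27280 by 2.08 ± 0.36 and WRKY53 by 1.92 ± 0.41. The expansin gene EXPA8 rose by 2.2 ± 0.39, from 217 ± 102 to 979 ± 71.6 (adjusted p = 0.00069). AT2G20870 rose by 2.61 ± 0.49 (adjusted p = 0.001), AT5G22430 by 2.01 ± 0.46 (adjusted p = 0.0053) and COR15A by 1.74 ± 0.4 (adjusted p = 0.0055).

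At that time 3 of 4 touch and rapid stress genes fell in shoots (4 adjusted over the list alone, median -1.54, adjusted p = 0.0023, adjusted p = 0.42 with an estimated correlation). The heat shock gene AT5G48570 fell by 1.44 ± 0.37 (1 of 5, 1 adjusted over the list alone, median -0.92, adjusted p = 0.11), PYK10 by 0.92 ± 0.27 (1 of 3, 1 adjusted over the list alone, -0.34, adjusted p = 0.28). UGT74B1 rose by 0.51 ± 0.14 (1 of 3 glucosinolate genes, 1 adjusted over the list alone, 0.34, adjusted p = 0.15). COR15A was the 1 of 4 abscisic acid, drought and cold genes that passed (2 adjusted over the list alone, 1 of them down, median 0.04, adjusted p = 0.9). Photosynthesis, flavonoid and auxin genes had medians of 0.21, 0.39 and 0.05 and adjusted p = 0.33, 0.34 and 0.7. They had 0 members past the limma threshold (0, 1 and 1 at an unadjusted p under 0.05, and 0, 0 and 1 adjusted over the list alone). The auxin mean of -0.15 and its test pointed down. Among the added lists, 5 of 11 sugar starvation genes (median -0.93, adjusted p = 1.7e-06), 11 of 41 peroxidases (-0.33, 0.0021), 11 of 97 ribosomal protein genes (-0.17, 7.4e-09), 4 of 23 hypoxia genes (-0.43, 0.015) and 3 of 5 WRKY genes (-1.13, 0.002) fell. These had adjusted p = 0.44, 0.43, 0.58, 0.81 and 0.42 with an estimated correlation. The actin 3' to 5' ratio was 3.38 ± 0.000707 at 24 h and 2.58 ± 0.0721 at 0 h. Without shoot 0 h replicate 1, 24 h replicate 1 or 24 h replicate 2 the 2344 probe sets became 702, 953 and 1188 and the rapid stress genes 5, 9 and 9. In shoots alone 1541 probe sets passed. AT2G43620 lost its call without each of these 3 arrays, AT4G01870 without these or 0 h replicate 2, AT5G22430 without 0 h replicate 1 or 24 h replicate 2 and COR15A without 0 h replicate 1. Their adjusted p reached 0.49, 0.099, 0.13 and 0.13 over all alternatives. AT2G43620, AT5G22430 and COR15A also lost their call without a pseudocount, and AT2G43620 and AT4G01870 in shoots alone.

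In roots, 2657 probe sets changed over the day. The phosphatase-family gene AT3G16800 had the largest F (68.3) among the named genes and ranged over 2.45, from 75 ± 4.27 (SD, n = 2) at 12 h to 455 at 24 h. The transporter gene OCT1 (AT1G73220) ranged over 2.64, between 0.973 ± 0.361 at 12 h, a signal near the background, and 58.5 ± 2.17 at 24 h. AT4G33980 ranged over 3.07 with its highest signal at 6 h (112 ± 29.7), and the clock gene GI over 1.71, from 99.3 ± 4.22 at 12 h to 348 ± 22.4 at 4 h. The defensin gene PDF2.1 (AT2G02120) ranged over 2.69, from 58 ± 13.3 at 1 h to 425 ± 40.6 at 4 h, a call lost without a pseudocount (adjusted p = 0.086). AT2G16365, AT1G70880 and AT2G23910 complete the 8 genes, with F of 51.3, 36.9 and 36.3.

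At 0.25 h in roots, the changes up were led by mitochondrial and plastid genes. The mitochondrial genes nad4 and nad5 rose by 2 ± 0.31 (192 ± 12.6 to 798 ± 85.6, SD, n = 2; adjusted p = 0.00081) and 2.01 ± 0.41 (adjusted p = 0.0087). The plastid genes psaA and psaC rose by 1.74 ± 0.31 and 1.7 ± 0.23. AT1G15270 fell by 1.43 ± 0.15 (adjusted p = 2.1e-05) and AT3G47260 by 1.26 ± 0.32 (adjusted p = 0.025). Of the plastid genome, 8 of 33 photosynthesis genes rose and 1 fell (median 0.65, adjusted p = 3.5e-09, adjusted p = 0.48 with an estimated correlation). So did 8 of 19 gene expression genes (0.82, 5.1e-08, adjusted p = 0.42 with an estimated correlation) and 3 of 10 NDH genes (0.29, 0.0019, adjusted p = 0.57 with an estimated correlation). Of the mitochondrial genes 7 of 12 rose (1.03, 4e-05, adjusted p = 0.42 with an estimated correlation). The 25S rRNA signal was 1286 ± 107.5 at 0 h and 2590 ± 57.3 at 0.25 h, and the actin 3' to 5' ratio was 2.41 ± 0.151 and 1.59 ± 0.0749.

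In the same comparison 461 probe sets were higher and 342 lower. Smaller list changes were those of the ribosomal protein (6 of 97 lower), rapid stress (2 of 23 higher), sugar starvation (1 of 11 higher) and diurnal genes (0 of 12 past the limma threshold, 5 at an unadjusted p under 0.05). They had adjusted p = 0.0053, 0.047, 0.0062 and 0.018 and adjusted p = 0.83, 0.83, 0.67 and 0.44 with an estimated correlation. With the 25S rRNA covariate the count was 0 with limma (1284 at an unadjusted p under 0.05). The genes nad4, nad5, AT1G15270 and AT3G47260 then had adjusted p = 0.52, 0.86, 0.14 and 0.65. Without root 0 h replicate 2, 0.25 h replicate 1 or 0.25 h replicate 2 the 803 probe sets became 111, 333 and 270 and the mitochondrial genes 1, 3 and 1 (3 without 0 h replicate 1). The plastid photosynthesis genes past the threshold became 3 without 0 h replicate 2, 5 without 0.25 h replicate 2 and 14 without either 24 h array. The call of nad5 was lost without 0 h replicate 2 or 0.25 h replicate 2 (adjusted p = 0.08 and 0.053), and that of AT3G47260 without these (0.17 and 0.25), without 0 h replicate 1 (0.06) or without a pseudocount.

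At 0.5 h in roots, the isocitrate lyase gene ICL rose by 1.65 ± 0.33 (adjusted p = 0.014, n = 2) and AT3G10020 by 1.19 ± 0.25 (adjusted p = 0.019). The plastid gene atpH fell by 1.8 ± 0.31 (369 ± 85.2 to 97.4 ± 7.29, SD; adjusted p = 0.0056) and AT3G33066 by 1.7 ± 0.34 (adjusted p = 0.014). In all 142 probe sets were higher and 104 lower (169 and 68 with arrays centred on their median, 119 and 132 with no filter, 19 and 3 without 0 h replicate 2). Of the plastid photosynthesis genes 6 of 33 fell and 1 rose (median -0.33, adjusted p = 0.019). Of the NDH genes 1 of 10 fell (adjusted p = 0.022), of the GSTU genes 1 of 10 (0.038) and of the ribosomal protein genes 3 of 97 (8.4e-06). The hypoxia genes had a median of 0.45 with 1 of 23 higher (adjusted p = 0.0042). Sugar starvation and diurnal genes had adjusted p = 0.00062 and 0.031 with 0 members past the limma threshold (5 and 6 at an unadjusted p under 0.05). These 7 lists had adjusted p = 0.83, 0.67, 0.42, 0.67, 0.77, 0.58 and 0.46 with an estimated correlation. Without root 0 h replicate 2, 0.5 h replicate 1 or 0.5 h replicate 2 the 246 probe sets became 22, 23 and 113, in roots alone 79 and with the 25S rRNA covariate 136. All 4 named genes lost their call without 0 h replicate 2 (adjusted p = 0.11, 0.17, 0.092 and 0.16). ICL also lost it without 0 h replicate 1 or 0.5 h replicate 1 (0.057 and 0.21), AT3G10020 (0.12 and 0.065) and AT3G33066 (0.067 and 0.078) without either 0.5 h array, and these 3 in roots alone.

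At 1 h and 3 h in roots, genes of the response to low oxygen rose. AT3G10040, an attenuator of the hypoxia response, rose by 4.14 ± 0.42 at 1 h, from 38.9 ± 21.3 to 872 ± 450 (SD, n = 2; adjusted p = 7.9e-06), and by 2.75 ± 0.42 at 3 h. The calmodulin-like gene CML38 (AT1G76650) rose by 3.2 ± 0.55 at 1 h (41.3 ± 28.5 to 494 ± 366, adjusted p = 0.0011). At this time AT4G24110 rose by 2.9 ± 0.48, AT1G33055 by 2.67 ± 0.47, AT4G10270 by 2.64 ± 0.41, AT3G23170 by 2.62 ± 0.31 and the pyruvate decarboxylase gene PDC2 by 1.59 ± 0.38. At 3 h AT5G10040 rose by 3.48 ± 0.67 (42.7 ± 13.9 to 569 ± 33.6, adjusted p = 0.0029) and AT3G29970 by 3.43 ± 0.64. AT2G17850 rose by 3.25 ± 0.49, PDC2 by 2.19 ± 0.38 and AT3G03270 by 1.17 ± 0.29. Of the 23 genes of the wider hypoxia list, 15 rose at 1 h (median 1.59, adjusted p = 1.1e-21) and 20 at 3 h (1.5, 8.3e-23). Both had adjusted p = 0.36 with an estimated correlation. At 3 h the small heat shock genes AT1G53540, AT5G37670 and ATHSP22.0 rose by 2.61 ± 0.62, 1.62 ± 0.37 and 1.57 ± 0.37 (3 of 5, 3 adjusted over the list alone). The list had a median of 1.57 and adjusted p = 0.0011 (adjusted p = 0.42 with an estimated correlation). The germin-family gene AT5G38910 fell by 3.81 ± 0.69 at 1 h (adjusted p = 0.0017) and AT2G30670, AT1G26380 and AT3G28510 by 2.19 ± 0.55, 2.07 ± 0.55 and 1.94 ± 0.45. At 3 h AT1G73120 fell by 2.56 ± 0.63 and AT3G12900 by 1.7 ± 0.43.

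The counts in roots were 585 higher and 609 lower at 1 h and 655 and 568 at 3 h (827 and 307, and 778 and 395, with arrays centred on their median). The 25S rRNA signal was 2332 ± 30.4 and 2464 ± 71.4. Without root 0 h replicate 1, 0 h replicate 2, 1 h replicate 1 or 1 h replicate 2 the 1194 probe sets at 1 h became 490, 647, 225 and 524 (145 higher and 80 lower for the 225). The hypoxia genes became 9 without 0 h replicate 1 and 5 without 1 h replicate 1. Without 0 h replicate 2, 3 h replicate 1 or 3 h replicate 2 the 1223 at 3 h became 258, 342 and 294, the hypoxia genes 13, 11 and 10 (13 without 0 h replicate 1) and the heat shock genes 0, 1 and 0. CML38 and AT1G33055 lost their call without 1 h replicate 1 (adjusted p = 0.055 and 0.057). AT2G30670 and AT3G28510 lost it without 0 h replicate 1 or either 1 h array, and AT1G26380 without 0 h replicate 2 or either 1 h array (adjusted p up to 0.27, 0.38 and 0.44 over all alternatives). At 3 h AT1G73120 and AT3G12900 lost it without 0 h replicate 2 or either 3 h array (up to 0.17 and 0.31). With the 25S rRNA covariate 67 and 162 probe sets and 3 and 4 hypoxia genes passed at 1 and 3 h, and no heat shock gene did at 3 h. The heat shock median moved from 1.57 to 1.62 and its median SE from 0.37 to 0.55, so these calls ended through the wider error. The hypoxia medians shrank from 1.59 to 1.38 and from 1.5 to 1.26, with SE growing from 0.35 to 0.5 and 0.52. AT3G10040 at 1 h kept its call, while AT4G24110, AT1G33055, AT5G38910, AT5G10040 and AT3G29970 had adjusted p = 0.056, 0.075, 0.073, 0.12 and 0.13, and the other falls named at 1 and 3 h lost their calls. Without a pseudocount 9 and 13 hypoxia genes and 1 heat shock gene passed, as did 1 heat shock gene with the stricter filter, and AT4G24110, AT1G26380, AT3G28510, AT5G10040 and AT1G73120 lost their calls. In roots alone AT2G30670 at 1 h and AT3G12900 at 3 h lost theirs.

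Of the fixed lists at 1 h in roots, the abscisic acid, drought and cold genes LTI30 and COR47 rose by 1.4 ± 0.23 and 1.27 ± 0.27 (2 of 4, 2 adjusted over the list alone). The list had a median of 0.53 and adjusted p = 0.048 (adjusted p = 0.47 with an estimated correlation). CML38 was the 1 of 4 touch and rapid stress genes that passed (2 adjusted over the list alone, 1 of them down, adjusted p = 0.92). The median of this list, -0.6, had the opposite sign to its mean of 0.29 and its test. UGT78D1 fell by 0.74 ± 0.23 (1 of 3 flavonoid genes, 1 adjusted over the list alone, median -0.54, adjusted p = 0.48). Heat shock, photosynthesis, root marker, glucosinolate and auxin genes had 0 members past the limma threshold (1, 0, 0, 1 and 0 at an unadjusted p under 0.05, 0 adjusted over the list alone). They had medians of 0.26, 0.15, 0.21, -0.15 and -0.3 and adjusted p = 0.88, 0.39, 0.44, 0.83 and 0.68. The heat shock mean was -0.05 and the glucosinolate test pointed up. Among the added lists at 1 h, 3 of 12 diurnal genes (adjusted p = 0.0038), 2 of 11 sugar starvation genes (0.0017), 8 of 33 plastid photosynthesis genes (2 fell, 0.00068) and 4 of 19 plastid gene expression genes (0.002) rose. Of the xyloglucan hydrolase genes 0 of 7 passed limma's threshold (3 at an unadjusted p under 0.05, adjusted p = 0.047). These lists had adjusted p = 0.42, 0.63, 0.72, 0.66 and 0.44 with an estimated correlation. The 25S rRNA signal was 2332 ± 30.4 at 1 h against 1286 ± 107.5 at 0 h, and the actin 3' to 5' ratio 1.74 ± 0.075 against 2.41 ± 0.151. An RNA preparation difference was therefore not excluded for the plastid genes at 1 h. At 3 h 6 of 12 diurnal genes rose (median 0.58, adjusted p = 1.1e-08, adjusted p = 0.046 with an estimated correlation), as did 3 of 11 sugar starvation genes (0.56, 0.00058, adjusted p = 0.58 with an estimated correlation). At the same time 6 of 97 ribosomal protein genes (adjusted p = 0.019) and 2 of 10 GSTU genes (0.048) fell, with adjusted p = 0.84 and 0.42 with an estimated correlation.

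**Figure D3:**
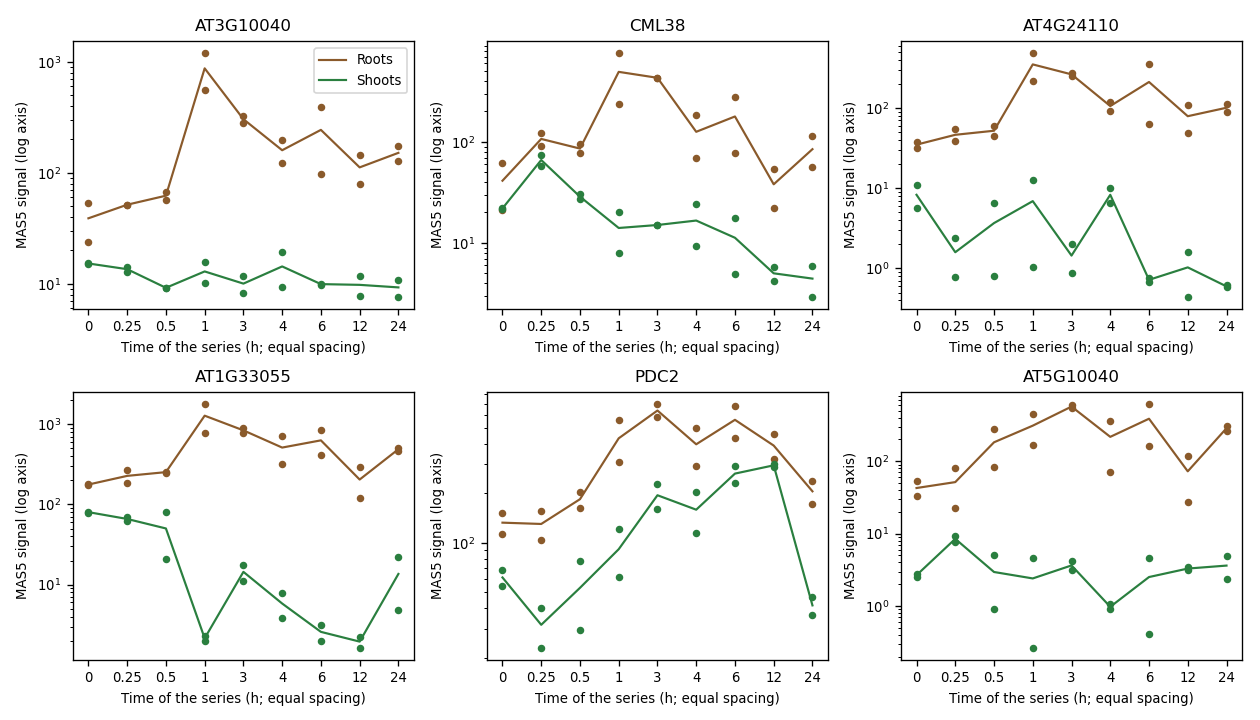
MAS5 signal (log scale) of 6 genes of the wider hypoxia list in shoots and roots at the 9 sampling times, spaced equally; points are single arrays and lines join the means of 2 arrays. In roots AT3G10040 averaged 38.9 at 0 h and 872 at 1 h.

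**Figure D4:**
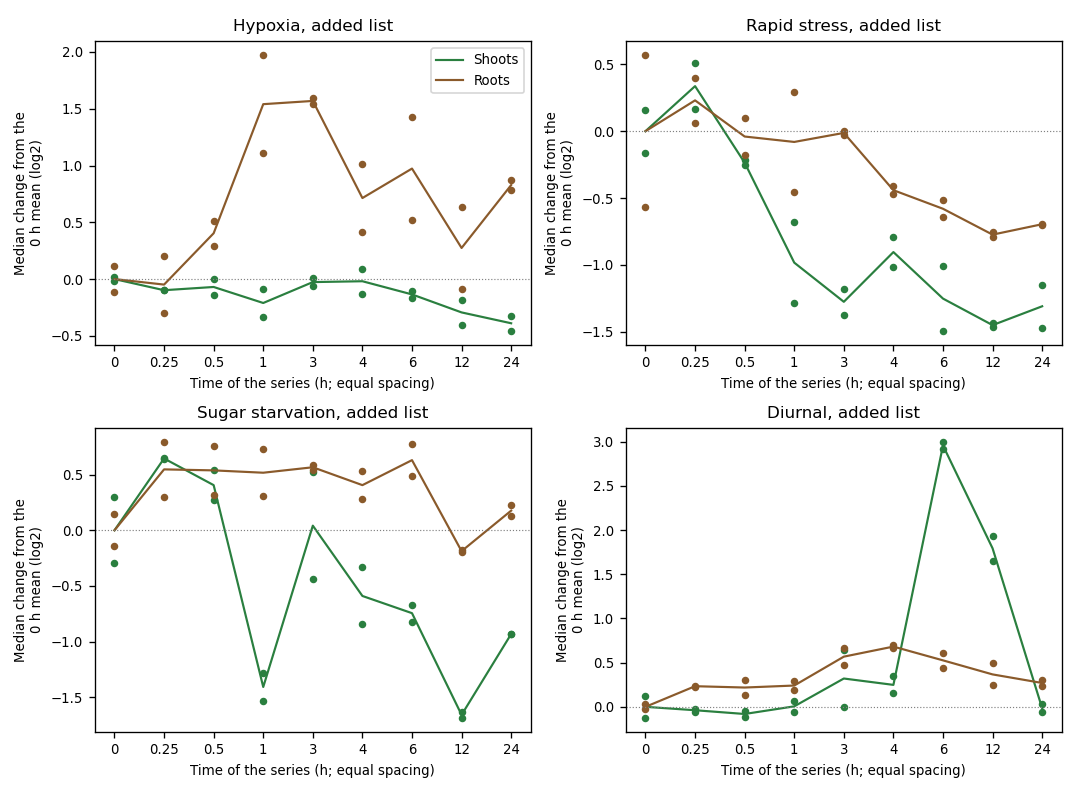
Median log2 change from the 0 h mean over the genes of 4 added lists, with a point for each array and lines through the means of 2 arrays, shoots in green and roots in brown, at the 9 times spaced equally. The hypoxia genes had a median change of 1.59 in roots at 1 h, and the rapid stress genes one of -1.31 in shoots at 24 h.

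At 4 and 6 h in roots, genes with a daily rhythm were among the most changed. AT4G33980 rose by 2.32 ± 0.22 at 4 h and 3.07 ± 0.22 at 6 h (4.29 ± 0.356 to 112 ± 29.7, SD, n = 2; adjusted p = 1.1e-06 and 8.6e-09). From a 0 h signal this near the background, the rise ran from 1.04 to 3.84 at 4 h and from 1.56 to 4.68 at 6 h over all alternatives. AT1G11210 rose by 2.17 ± 0.25 at 4 h (0.93 to 3.8 over all alternatives), and GI by 1.11 ± 0.13 and 0.95 ± 0.13. Of the wider diurnal list 5 and 6 of 12 genes rose (medians 0.6 and 0.51, adjusted p = 8.2e-10 and 7.3e-10, adjusted p = 0.034 with an estimated correlation at both times). OCT1 fell by 2.13 ± 0.19 at 6 h (adjusted p = 2.7e-07; -5.03 to -0.81 over all alternatives), AT1G73120 by 3.32 ± 0.63 and 2.85 ± 0.63, and AT3G12900 by 1.92 ± 0.43 at 4 h. Hypoxia genes were higher than at 0 h, 4 and 8 of 23 (medians 0.71 and 0.99, adjusted p = 6.2e-08 and 1.2e-13, adjusted p = 0.51 and 0.42 with an estimated correlation). AT5G10040 was higher by 2.66 ± 0.67 at 6 h (42.7 ± 13.9 to 387 ± 317, adjusted p = 0.02), with a wide spread between its 2 arrays. At 6 h 4 of 23 rapid stress genes fell (median -0.57, adjusted p = 8.9e-05, adjusted p = 0.63 with an estimated correlation).

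In these comparisons 373 probe sets were higher and 360 lower at 4 h (446 and 228 with arrays centred on their median) and 452 and 366 at 6 h. At 4 h 8 of 97 ribosomal protein genes fell. At this time 2 of 11 sugar starvation, 6 of 33 plastid photosynthesis and 3 of 19 plastid gene expression genes and 1 of 12 mitochondrial probe sets rose. The 25S rRNA signal was 2198 ± 124.5 at 4 h and 1933 ± 369.1 at 6 h against 1286 ± 107.5 at 0 h, and the actin 3' to 5' ratio 2.06 ± 0.166 and 2.13 ± 0.173 against 2.41 ± 0.151. An RNA preparation difference was therefore not excluded for the plastid and mitochondrial genes at these times. The 5 lists at 4 h had adjusted p = 0.00027, 0.0011, 1.4e-05, 0.0013 and 0.041 (adjusted p = 0.76, 0.59, 0.64, 0.64 and 0.69 with an estimated correlation). At 6 h 6 ribosomal protein genes fell and 3 sugar starvation, 4 plastid photosynthesis and 1 plastid gene expression genes rose. Their adjusted p was 2.3e-06, 0.00012, 0.0071 and 0.027 (adjusted p = 0.67, 0.52, 0.8 and 0.77 with an estimated correlation). Without root 0 h replicate 2 the counts of 733 and 818 became 112 and 254, and with the 25S rRNA covariate 86 and 353. Without 4 h replicate 2 the count at 4 h was 156, and without 6 h replicate 1 or 2 that at 6 h was 357 and 514. AT1G73120 lost its calls without 0 h replicate 2 (adjusted p = 0.063 and 0.083) and at 6 h without 6 h replicate 1 (0.13). AT3G12900 lost it without 0 h replicate 2 or either 4 h array, and AT5G10040 without either 0 h array or 6 h replicate 1 (adjusted p up to 0.28 and 0.27 over all alternatives). The covariate ended the calls of AT1G73120 at 4 h, AT3G12900 and AT5G10040. In roots alone AT3G12900 and AT5G10040 lost theirs as well, and AT5G10040 also without a pseudocount.

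At 12 h in roots AT2G23910 rose by 2.24 ± 0.22, from 48.4 ± 2.9 to 267 ± 15.1 (SD, n = 2; adjusted p = 5.4e-07). The glycosyltransferase genes AT2G22590 and UGT84A1 rose by 2.08 ± 0.24 and 1.88 ± 0.19 and PDF2.1 by 1.86 ± 0.21. AT3G16800 fell by 2.11 ± 0.13 (358 ± 24.7 to 75 ± 4.27, adjusted p = 2.7e-10), OCT1 by 2.16 ± 0.19 (-5.36 to -0.81 over all alternatives), AT2G28780 by 2.09 ± 0.19 and AT1G73120 by 2.8 ± 0.63. In all 323 probe sets were higher and 250 lower (406 and 198 with arrays centred on their median). CML23 fell by 1.34 ± 0.29 (1 of 4 touch and rapid stress genes, 1 adjusted over the list alone). The list had a median of -1 and adjusted p = 0.045 (adjusted p = 0.59 with an estimated correlation). RCA fell by 0.62 ± 0.14 (1 of 7 photosynthesis genes, 1 adjusted over the list alone, median -0.27, adjusted p = 0.075). UGT78D2 rose by 0.92 ± 0.16 (1 of 3 flavonoid genes, 1 adjusted over the list alone, median 0.35, adjusted p = 0.071). Heat shock, abscisic acid, drought and cold, root marker, glucosinolate and auxin genes had 0 members past the limma threshold (1, 0, 0, 0 and 0 at an unadjusted p under 0.05, 0 adjusted over the list alone). They had medians of 0.08, -0.02, -0.27, -0.14 and 0.13 and adjusted p = 0.81, 0.9, 0.63, 0.74 and 0.99. The mean had the other sign for the heat shock (-0.15), abscisic acid (0.02) and auxin lists (-0.01). The test followed the mean for the heat shock and abscisic acid lists and the median for the auxin list.

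Of the added lists at 12 h in roots, 3 of 23 rapid stress genes fell (median -0.76, adjusted p = 1.3e-07, adjusted p = 0.48 with an estimated correlation). Of the diurnal genes 3 of 12 rose and 2 fell (0.37, 0.0099, adjusted p = 0.42 with an estimated correlation) and 1 of 23 hypoxia genes rose (0.13, 0.037, adjusted p = 0.83 with an estimated correlation). The count of 573 was 162 without root 0 h replicate 2, 172 and 233 without 12 h replicate 1 or 2 and 317 with the 25S rRNA covariate. AT1G73120 lost its call without 0 h replicate 2 or 12 h replicate 1 (adjusted p = 0.13 and 0.16) and, like AT2G22590 (0.099), UGT84A1 (0.068), PDF2.1 (0.32) and AT2G28780 (0.093), without a pseudocount.

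At 24 h in roots, 218 probe sets were higher and 87 lower than at the same hour a day earlier. AT3G29970 rose by 2.75 ± 0.64 (adjusted p = 0.027, n = 2), AT2G17850 by 2.31 ± 0.49 (0.019), AT3G10040 by 1.78 ± 0.42 (0.03) and ICL by 1.71 ± 0.33 (0.011). Of the hypoxia genes 2 of 23 rose (median 0.85, adjusted p = 6.8e-12, adjusted p = 0.42 with an estimated correlation). AT1G36640 fell by 1.37 ± 0.16 (167 ± 2.89 to 58.7 ± 5.14, SD; adjusted p = 0.00014), AT1G15270 by 1.2 ± 0.15 (0.00041), AT5G19890 by 1.57 ± 0.34 (0.021) and AT3G01260 by 1.4 ± 0.35 (0.038). No fixed list passed. Touch and rapid stress, heat shock, abscisic acid, photosynthesis, root marker, flavonoid, glucosinolate and auxin genes had medians of -0.81, 0.28, 0.13, 0.13, -0.18, -0.2, -0.29 and 0.45 and adjusted p = 0.26, 0.52, 0.69, 0.061, 0.68, 0.88, 0.28 and 0.56. They had 0 members past the limma threshold (2, 0, 0, 2, 0, 0, 1 and 0 at an unadjusted p under 0.05, and 2, 0, 0, 1, 0, 0, 0 and 0 adjusted over the list alone). The rapid stress list had a median of -0.73 (adjusted p = 2.5e-05) with 0 of 23 genes past limma's threshold (9 at an unadjusted p under 0.05). Ribosomal protein (2 lower), diurnal (1 higher), plastid photosynthesis (1), plastid gene expression (1) and mitochondrial genes (1) had adjusted p = 2.6e-06, 0.022, 0.024, 0.037 and 0.029. These 6 lists had adjusted p = 0.59, 0.67, 0.44, 0.83, 0.79 and 0.67 with an estimated correlation. The 25S rRNA signal was 1950 ± 579.1 at 24 h against 1286 ± 107.5 at 0 h, and the actin 3' to 5' ratio 1.93 ± 0.529 against 2.41 ± 0.151. An RNA preparation difference was therefore not excluded for the plastid and mitochondrial genes. The count of 305 became 38 without root 0 h replicate 2, 16 without 24 h replicate 2, 18 with the 25S rRNA covariate, 122 in roots alone and 463 with the larger pseudocount. AT3G29970, AT3G10040, AT5G19890 and AT3G01260 lost their call without 0 h replicate 2 or either 24 h array, AT2G17850 without any of the 4 arrays and ICL without 0 h replicate 2 or 24 h replicate 2. Their adjusted p reached 0.24, 0.34, 0.37, 0.45, 0.13 and 0.1 over all alternatives, and each also lost its call in roots alone and with the covariate. AT1G36640 lost its call without a pseudocount (0.13), as did AT3G29970 and AT3G01260. AT3G01260 also lost its call without the filter.

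The tissues differed in their time course for 6171 probe sets (40.9%). AT1G70820, AT3G62550, AT1G55960, AT3G28270 and AT1G07050 ranged over 3.21, 4.95, 4.18, 4.35 and 4.79 on the log2 scale in shoots. In roots AT1G70820, AT3G62550, AT3G28270 and AT1G07050 had mean signals of at most 0.949, 12.4, 2.19 and 6.43, below the filter of 40, so a change there could not be read. AT1G55960 had root signals of 64.5 ± 1.42 to 78 ± 1.59, a range of 0.24 (limma F-test, adjusted p = 0.91). DPE1 and CHL ranged over 3.46 and 3.37 in shoots and over 0.66 and 0.81 in roots, and AT4G16146 over 3.94 and 1.12. The number of probe sets whose change from 0 h differed between the tissues was 264 at 0.25 h, 183 at 0.5 h, 1680 at 1 h, 2443 at 3 h, 1504 at 4 h, 3158 at 6 h, 3118 at 12 h and 1236 at 24 h.

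Of the 20 fixed lists, 12 had fewer than 3 kept genes that the probe table named and were not tested, and 5 of these had none. Other genes of these lists may have values among the 8794 probe sets that the table left without a gene. Beyond the genes already given, AKINBETA1 of the sugar starvation list rose by 0.88 ± 0.2 at 0.25 h in shoots and fell by 1.3 ± 0.2 at 12 h. In shoots OPCL1 of the jasmonate list rose by 0.73 ± 0.2 at 0.25 h. The iron regulator PYE rose by 0.4 ± 0.12 at 12 h and fell by 0.58 ± 0.12 at 24 h in shoots. The cell division genes AUR1 and AUR2 were lower in shoots than in roots, by -0.71 ± 0.052 and -0.89 ± 0.06.

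**Figure D5:**
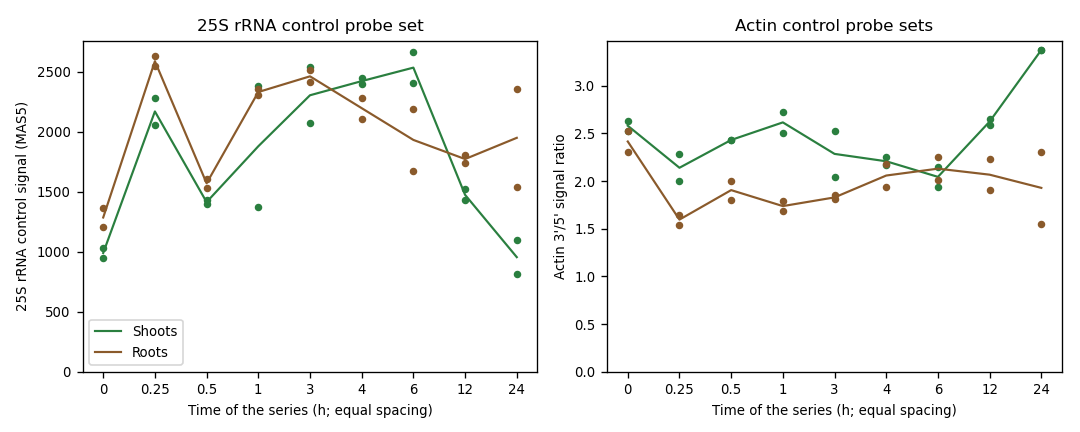
Signal of the 25S rRNA control probe set and 3' to 5' ratio of the actin control, by time (spaced equally) in shoots and roots; points are single arrays and lines join the means of 2 arrays. The 25S rRNA signal in roots was 1286 at 0 h and 2590 at 0.25 h.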

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

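All tests in this part were chosen only after the result was seen, except the counts of probe sets and genes whose time course differed between the tissues and the test of other splits of the arrays into shoots and roots.

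The time course differed between the tissues for 6171 probe sets, and the change from 0 h differed for 264 probe sets at 0.25 h, 183 at 0.5 h, 1680 at 1 h, 2443 at 3 h, 1504 at 4 h, 3158 at 6 h, 3118 at 12 h and 1236 at 24 h. The genes with the smallest p for this difference were AT1G70820 (F = 134), AT3G62550 (117), AT4G16146 (102), AT1G55960 (100), AT3G28270 (93.4), AT1G07050 (90.4), DPE1 (89.1) and CHL (82.1). In roots the signals of AT1G70820, AT3G62550, AT3G28270 and AT1G07050 were below the filter, so their F reflects the change in shoots, and the order depends on the pseudocount. Without it these 4 had F of 12.7, 47.1, 7.12 and 14.5, while DPE1 and CHL had at least 63.6 and 65.8 over all alternatives. Among gene lists, the change in shoots minus that in roots had a median of -0.74 at 1 h, -0.92 at 12 h and -0.58 at 24 h for the wider rapid stress list (adjusted p = 5.9e-08, 0.011 and 0.0029), and of -2.1 at 1 h and -1.17 at 12 h for sugar starvation genes (2.4e-12 and 1.9e-05). It was 2.05 for abscisic acid, drought and cold genes (0.024) and 0.95 for diurnal genes (0.022), both at 6 h, and -0.48 for ribosomal protein genes at 12 h (6.8e-20). For hypoxia genes it was -2.08 at 1 h and -1.37 at 3 h (5.8e-18 and 2.4e-12) and for heat shock genes -1.91 at 3 h (0.00093). Each of these list differences had adjusted p of at least 0.53 with an estimated correlation.

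The number of probe sets that separated shoots from roots was compared with other splits of the 36 arrays into 18 and 18. In a fit of split and time the real split gave 13599 probe sets, and 1 of 100 splits, the real one, gave as many. A split that mixes the tissues gives fewer calls where most probe sets differ between them, so this outcome was close to fixed. With 100 splits no share under 1 of 100 can be reached, so the test says little about chance. The highest other split gave 10038, with 13 shoot and 5 root arrays on one side, which points to the difference between the tissues as a structure of the samples, since the split follows it in part. The median of the other splits was 0.

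Hypoxia genes were higher in roots at 1 and 3 h than at 0 h, with medians of 1.59 and 1.5. Unusually low values on the 2 root 0 h arrays are argued against: the list was also higher at 1 and 3 h than at 0.25 and 0.5 h, by a median of 1.75 (quartiles 0.7 and 2.04) and in 23 of 23 genes, though against 24 h the medians were a smaller 0.49 (5 of 23 genes lower) at 1 h and 0.65 (23 of 23 higher) at 3 h. The RNA preparation difference that the 25S rRNA signal follows is argued against as the whole cause by the median of -0.03 at 0.25 h, where this signal was highest in roots. With that signal as a covariate the median moved from 1.59 to 1.38 at 1 h and from 1.5 to 1.26 at 3 h, while the median SE grew from 0.35 to 0.5 and 0.52, so that the calls ended mainly through the wider error, and 3 and 4 of 23 genes passed. Some of these genes also differed widely between the 2 root arrays of one time, such as AT3G10040 at 6 h (243 ± 208) and CML38 at 1 h (494 ± 366). At 3 h the arrays were closer for both (304 ± 32.4 and 431 ± 1.58). What stays open is an untested difference in harvest or handling between single times or single samples. A fall of oxygen around roots in the handled plants is a hypothesis that oxygen measured around the roots, or roots kept aerated while handled, would test.

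Stress genes were higher in shoots at 0 h than at 24 h, with a median change of -1.31 (quartiles -1.97 and -0.72, 21 of 23 genes lower). A single outlying 0 h array is argued against for the list as a whole, since the median was -1.07 against the weaker and -1.51 against the other 0 h array alone. The 2 arrays differed widely for some members, such as WRKY53 (81.8 ± 72.4), so this does not hold for each gene. A difference in harvest confined to 0 h is argued against too, since 24 h was also lower than 0.25 h by a median of -1.81 (quartiles -2.24 and -0.92, 23 of 23 genes). The more 3' biased RNA of the 24 h shoot arrays, as read from actin, is argued against by the median of -0.94 or lower at 1 and 12 h. The actin ratios of these times were close to that of 0 h. The ubiquitin 3' to 5' ratio did not follow actin: it was 1.955 ± 0.0311 at 0 h and 1.947 ± 0.0141 at 24 h. At 1 and 12 h it was 2.118 ± 0.199 and 2.365 ± 0.00141. By ubiquitin 24 h was not more 3' biased than 0 h but 12 h was, so the match of 12 h to 0 h holds for actin only. Root material in the shoot 0 h samples is argued against, since the fall would need a median share of root RNA of 42.5% (lower quartile 18.8%), and the share measured on the 0 h shoot arrays was at most 5.34%. A stress of the plants at the start of the experiment may have raised these genes at 0 and 0.25 h, but this series holds no samples from before 0 h to test it, and a difference in harvest between these first samples and the later ones cannot be separated from time.

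Transcripts of the plastid and mitochondrial genomes were higher in roots at 0.25 h than at 0 h, with medians of 0.65 and 1.03. Over the 9 root group means the smaller r of these lists with the log2 25S rRNA signal was 0.52 (exact permutation p = 0.15, adjusted 0.17, rho = 0.57; 8 relations in the family), and the r nearer to 0 with the log2 actin 3' to 5' ratio was -0.49 (exact permutation p = 0.17, adjusted 0.17, rho = -0.43). Without the 0 and 0.25 h means these became 0.36 and -0.03, so in roots both relations rest on those means, and an RNA preparation difference and 3' bias cannot be told apart from a change of the transcripts. In shoots the plastid list followed both measures, with r = 0.86 (exact permutation p = 0.0039, adjusted 0.015, rho = 0.85) and r = -0.9 (p = 0.00047, adjusted 0.0038, rho = -0.93) and 0.82 and -0.85 without the 2 means farthest out, while the r of 0.7 and -0.74 of the mitochondrial list (exact permutation p = 0.029 and 0.03, rho = 0.88 and -0.83, and 0.6 and -0.69 without 2 means) missed the threshold with adjusted p = 0.06 each. With the 25S rRNA covariate the medians in roots at 0.25 h moved from 1.03 to 0.23 and from 0.65 to -0.17 (median SE 0.26 to 0.32 and 0.25 to 0.33), so the calls ended because the change itself shrank, which may reflect RNA preparation.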

How the results depend on the processing

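The 25S rRNA covariate and the counts for gene lists were chosen only after the data were seen, and the other alternatives before. With this covariate the counts in shoots were 129 at 0.25 h, 678 at 1 h, 1083 at 3 h, 842 at 4 h and 1950 at 6 h. In roots they were 0 at 0.25 h with limma (1284 at an unadjusted p under 0.05), 136 at 0.5 h, 67 at 1 h, 162 at 3 h, 86 at 4 h, 353 at 6 h, 317 at 12 h and 18 at 24 h. A fit of 1 tissue alone gave 500 in shoots at 0.5 h and 1541 at 24 h, and 79 in roots at 0.5 h and 122 at 24 h, where the larger pseudocount gave 463. Why the counts moved was not tested, though the single-tissue fit leaves fewer degrees of freedom. Lost degrees of freedom do not account for the effect of the covariate. Replicate number as a fixed term also adds a term, yet it kept all 128 named values, against 98 with the covariate. In lists that lost members, the covariate widened the error or shrank the change. In roots the median SE of the hypoxia list grew from 0.35 to 0.5 at 1 h. The mitochondrial median at 0.25 h shrank from 1.03 to 0.23. With an estimated correlation 3 list tests passed in place of 128. A replicate block, fixed or random, gave 13908 and 13895 probe sets for shoots against roots, close to the 13907 without pairing, and the random block correlation was -0.0261. Without single arrays the counts ranged from 13847 to 13897 for shoots against roots, 8600 to 9593 for the shoot and 1871 to 2883 for the root time course, and 5363 to 6578 for the interaction. Against 0 h in shoots they were 912 to 2290 at 0.25 h, 241 to 1329 at 0.5 h, 869 to 1875 at 1 h, 2206 to 3810 at 3 h, 2013 to 3271 at 4 h, 3905 to 5306 at 6 h, 3542 to 5272 at 12 h and 702 to 2707 at 24 h. In roots they were 111 to 916, 22 to 274, 225 to 1299, 258 to 1342, 112 to 804, 254 to 922, 162 to 640 and 16 to 313 at the same times. Among 128 named values 80 passed under each of the 12 other settings run for them and all 36 left-out arrays (the stricter filter left 118 to test and the fit of 1 tissue 104), 48 were lost under at least 1, 3 of them only without single arrays, and 0 reversed in direction. Members of lists were followed as counts only. Signals near the background, where the pseudocount decides the log2 value, limit some named genes: 20 of the 128 calls were lost without a pseudocount, and of 88 named changes against 0 h 41 moved by over 1.5 times in log2 size under at least 1 alternative.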

Other observations

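No explanation was tested in this part, and its genes and lists were chosen only after their values were seen.

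At 12 h in shoots 6 of 7 xyloglucan hydrolase genes were lower than at 0 h (median -1.01, adjusted p = 0.00079, adjusted p = 0.36 with an estimated correlation), XTH18 by -2.19 ± 0.37 SE, XTH19 by -1.8 ± 0.21, XTH32 by -1.11 ± 0.2, XTH33 by -1.01 ± 0.26, XTH16 by -0.85 ± 0.14 and XTH20 by -0.58 ± 0.18. The list also passed at 6 h (3 lower, median -0.59, adjusted p = 0.023) and 24 h (3 lower and 1 higher, -0.36, 0.024), each with adjusted p = 0.42 with an estimated correlation. Of the serine carboxypeptidase genes 7 of 17 were higher at 12 h and 1 lower (median 0.36, adjusted p = 0.006, adjusted p = 0.42 with an estimated correlation), led by SCPL49 at 2.62 ± 0.13, scpl35 at 1.75 ± 0.18 and scpl20 at 1.64 ± 0.1. At 6 h 7 of 15 cell division and histone genes were higher (median 0.5, adjusted p = 0.024, adjusted p = 0.76 with an estimated correlation), with AT2G28720 at 2.11 ± 0.15 and 3xHMG-box2 at 1.25 ± 0.22. SWEET2 was lower at 6 h by -2.73 ± 0.23, and 3 of 7 RALF genes were lower at 4 h (median -0.36, adjusted p = 0.044, adjusted p = 0.42 with an estimated correlation).

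Other shoot lists past the threshold were the WRKY genes at 3, 4 and 6 h (3 of 5 lower, adjusted p = 0.0021, 0.024 and 0.021, adjusted p = 0.42, 0.44 and 0.44 with an estimated correlation) and the peroxidases at 3 h (8 of 41 lower and 3 higher, 0.037, adjusted p = 0.59 with an estimated correlation). Plastid photosynthesis genes were higher at 4 h (8 of 33, adjusted p = 0.026) and 6 h (12, 0.0013), NDH genes at 4 h (4 of 10, 0.041) and 6 h (5, 0.048), and sugar starvation genes lower at 4 h (2 of 11, 0.023). These 5 had adjusted p = 0.83, 0.74, 0.72, 0.74 and 0.74 with an estimated correlation. The shoot 25S rRNA signal was 2424 ± 37.5 and 2536 ± 181 at 4 and 6 h against 990.1 ± 60.7 at 0 h, and the actin 3' to 5' ratio 2.21 ± 0.0622 and 2.04 ± 0.148 against 2.58 ± 0.0721, so RNA preparation was not excluded for the plastid and NDH genes.

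In roots 4 of 16 TBL wall acetylation genes were lower at 3 h (median -0.32, adjusted p = 0.0071, adjusted p = 0.44 with an estimated correlation): TBL30, TBL34, TBL28 and TBL21 by -0.7, -0.65, -0.55 and -0.49. RALFL24 and RALFL22 were lower at 3 h by -0.88 ± 0.14 and -0.57 (adjusted p of the list 0.034, and 0.029 at 4 h, adjusted p = 0.42 with an estimated correlation at both times). At 12 h UGT84A1, UGT78D2 and UGT72E2 were higher by 1.88, 0.92 and 0.86 and UGT76D1 lower by -0.85 (4 of 32 UGT genes, adjusted p = 0.028, adjusted p = 0.52 with an estimated correlation). The expansin, BGLU glucosidase and calmodulin-like lists passed in none of the 17 contrasts, although single members changed, such as EXLB1 at 1.8 ± 0.26 in shoots at 12 h and BGLU44 at 2.85 ± 0.19 in shoots at 6 h.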
